A study of Arabidopsis thaliana with 14 samples.

How the data were processed

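RNA from whole seedling roots of Arabidopsis thaliana was measured on Affymetrix expression arrays, with 2 arrays for each of 7 groups: standard medium and 3, 6, 12, 24, 48 and 72 h on iron-deficient medium. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was amplified in one cycle and labelled with biotin. The deposited values are probe set intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes, in a version that the sources used here do not give. The mean of each array without its lowest and highest 2% of probe sets was equal across the 14 arrays, a scaling that was kept. All 14 columns of values were matched to samples, with 0 left over. The number of arrays limits the precision of each value.

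The table held 22810 probe sets, of which 13513 were paired with 1 gene in the platform's probe table, 503 with several and 8794 with none. A table of reference genes served only to turn gene identifiers into locus names and symbols. The 64 control probe sets were left out of all tests. Values were transformed as log2(signal + 16), and the 40% of probe sets with the lowest mean were removed, which is a level of 49.6 in signal. The 13648 others were tested with limma 3.58.1 in R 4.3.3, with one mean per group, all 14 arrays in one fit with 7 residual degrees of freedom and a prior variance that follows the mean. Each iron-deficient group was compared with standard medium, and each time with the next. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. The F test of limma over the 6 comparisons with standard medium asked whether a probe set changed at any time.

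Genes were named by a rule set before the data were examined. At each time these are the 8 largest rises and the 8 largest falls by log2 fold change among called probe sets paired with 1 gene whose 2 arrays both lie on the same side of both control arrays. For neighbouring times the same rule takes 5 and 5, or fewer where fewer pass. Members of the lists fixed beforehand are also named whatever their value. Fixed lists were tested with camera at its preset correlation of 0.01 where at least 3 probe sets were tested, with Benjamini-Hochberg over all lists and times, beside camera with an estimated correlation and fry. These lists covered iron uptake and coumarin secretion, iron regulators, phenylpropanoid synthesis and other groups with fewer tested members, as well as cell type markers. Genes of these lists with no tested probe set were not analysed here. Further lists were made after the data had been seen, and were adjusted as a family of their own. They covered iron-responsive loci, cytosolic ribosomal proteins, photosynthesis, root hair cell wall and peroxidase genes, cell division, xylem and phloem, suberin, mitochondrial electron transport, hypoxia and 10 gene families.

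The overlap of calls between times was set beside unchanged groups simulated against the same 2 control arrays and beside the overlap of independent lists. The fit was tested on simulated data with 13648 genes, of which 100 changed 2-fold and 100 changed 4-fold. Between 64% and 77% of the 2-fold changes and between 99% and 100% of the 4-fold changes were recovered, with 4 to 13 false calls. The alternatives set beforehand were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, no trend, a robust prior, a fit of the 4 arrays compared, the replicate number as a block, a 2-fold threshold, adjustment over a whole family of comparisons, and leaving out each array in turn. Fits of the 10 arrays of the earlier set alone, comparisons within each array set, all alternatives for the overlap of calls, and quantile normalization and left-out arrays for the list tests were added after the data had been seen.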

Results

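RNA levels were measured in whole roots of Arabidopsis thaliana seedlings of the Columbia ecotype over a time course of iron deficiency. The series asks how root gene expression changes with time once iron is withdrawn. Seedlings grew for 5 days on standard medium and were then moved to a medium with no iron source that held 0.3 mM Ferrozine, a compound that binds ferrous iron. Roots were collected after 3, 6, 12, 24, 48 and 72 h on that medium. The only control was a group moved to fresh standard medium 3 h before harvest, so its handling matches that of the 3 h group alone. Each of the 7 groups held 2 arrays, each from a separate biological replicate of about 320 roots, which gave 14 arrays. The labels put every harvest into one 3 h window during the sixth day and also give 5 days of growth before the transfer. Both statements cannot hold for 48 and 72 h of treatment, so the age of those roots at harvest is not settled here.

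The Affymetrix arrays gave a linear signal for 22810 probe sets, with a median signal per array of 84.5 to 94.9. The 13648 probe sets above the filter on low signal were tested, of which 7356 were paired with 1 gene, 271 with several genes and 6021 with none in the platform table used. Fold changes are on the log2(signal + 16) scale, which understates the change of genes with low signal. The number of arrays, 2 per group, limits the precision of every comparison.

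The arrays fell into 2 sets that follow the time course. All 18 probe sets for the hybridisation spike-ins, which are added in fixed amounts to each sample, were lower on each of the 4 arrays of 48 and 72 h than on each of the other 10 arrays. Their geometric mean was 407 (378 to 440) at 48 and 72 h and 2796 (2172 to 3232) in the standard, 3, 6, 12 and 24 h groups, a 6.87-fold difference. The highest signal on an array was 11714 to 15134 in the later set and 27452 to 43173 in the earlier set. The correlation across probe sets between the 2 replicates of a group was 0.984 to 0.985 in the later set and 0.960 to 0.977 in the earlier set. The first principal component held 64.6% of the variance and ran from −32.2 to −12.0 in the earlier set and from 56.8 to 69.1 in the later set. No group had arrays in both sets, so each comparison of 48 or 72 h with standard medium, or of 24 h with 48 h, also compares the array sets, and no fit with the array set as a term can be had. Counts at 3 to 24 h are therefore also given from a fit of the 10 arrays of the earlier set alone, an alternative chosen after the data had been seen.

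**Figure D1:**
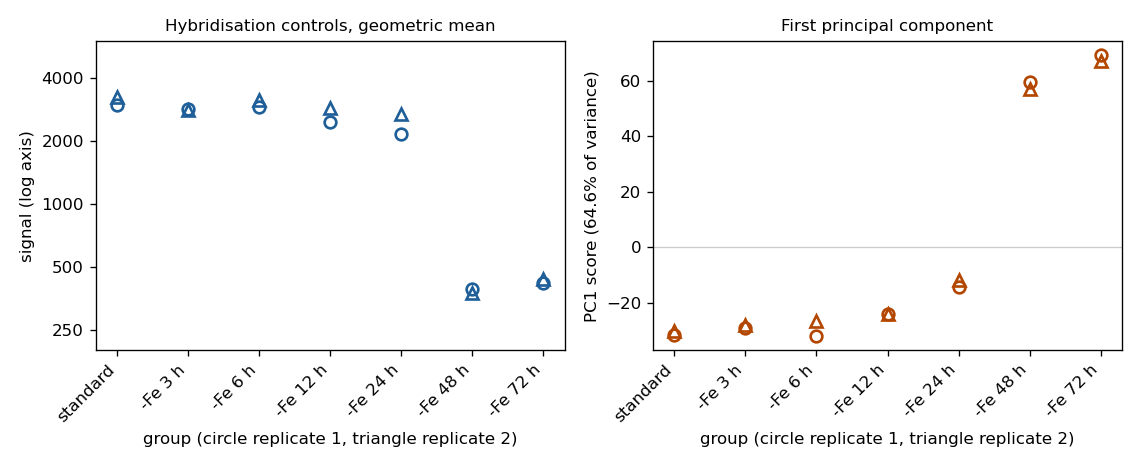
Geometric mean signal of the 18 hybridisation control probe sets (left, log axis) and score on the first principal component (right) for each of the 14 arrays, with 1 point per array. The 4 arrays of 48 and 72 h lie at 378 to 440 on the left and at 56.8 to 69.1 on the right, apart from the other 10 arrays.

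After 3 h without iron, 3 probe sets were higher than on standard medium and 0 were lower. They were IMA1 (AT1G47400), which encodes a peptide that promotes iron uptake, the acidic ribosomal protein gene AT4G00810, and a probe set with no gene in the table used. IMA1 rose from a signal of 151 ± 43.0 to 356 ± 76.3 (mean ± SD, n = 2), a log2 fold change of 1.17 ± 0.20 (SE). AT4G00810 rose by 1.12 ± 0.19 on the log2 scale, and both genes had an adjusted p of 0.0462. The unnamed probe set, chosen after its values were seen, rose by 1.67 with an adjusted p of 0.00337. In the fit of the earlier arrays alone, this probe set was the 1 called. The adjusted p was then 0.0791 for IMA1 and 0.0668 for AT4G00810. With limma, 993 probe sets had an unadjusted p under 0.05 at 3 h. The direction depended on single arrays. The count was 23 (15 higher and 8 lower) without standard replicate 2, 17 (3 higher and 14 lower) without replicate 2 of 3 h, 6, all higher, without standard replicate 1 and 1, higher, without any 1 of the other arrays. The root hair expansin gene EXPA18 was at −0.95 and EXPA7 at −0.77, and neither passed the test over all genes at this time.

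After 6 h, 129 probe sets had changed, 50 higher and 79 lower, of which 56 named 1 gene. The largest rises were in AT2G23270 (2.97 ± 0.34 on the log2 scale, adjusted p = 0.000109) and in AT1G26380, which encodes a berberine bridge enzyme-like oxidase (2.90 ± 0.26, adjusted p = 1.03e-05). AT3G18250 rose by 1.94, the peptide gene RALFL27 (AT3G29780) by 1.82, AT2G42660 by 1.75, AT1G10530 by 1.68, the calcium-binding protein gene AT5G39670 by 1.58 and the carboxylesterase gene AT1G68620 by 1.39. The largest fall was in AT4G21870, a small heat shock protein gene, at −2.75 ± 0.27 (adjusted p = 1.40e-05). AT2G41810 fell by 1.97, the bHLH gene AT2G43140 by 1.71, the aspartyl protease gene AT5G48430 by 1.67 and the extensin-like gene AT4G08410 by 1.49. The urease gene URE (AT1G67550) fell by 1.40, AT3G54040 by 1.30 and the receptor kinase gene AT1G05700 by 1.28. Of the iron genes fixed before the data were examined, BGLU42 (AT5G36890, 0.91), IMA1 (0.88) and the bHLH transcription factor gene bHLH101 (AT5G04150, 0.90) rose. In the 10 earlier arrays alone, 67 probe sets were called, 18 higher and 49 lower, and 66 of them were among the 129. The calls of AT2G42660, AT1G10530, AT5G39670, BGLU42, IMA1 and bHLH101 at 6 h were not kept there. Without standard replicate 1 the count was 67, with more higher (41) than lower (26), and without replicate 1 of 6 h it was 77 (20 and 57). The number of higher calls was 26 without replicate 2 of 6 h and 30 without either replicate of 48 h.

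After 12 h, 359 probe sets had changed, 146 higher and 213 lower, of which 172 named 1 gene. AT1G26380 (3.61 ± 0.26) and AT2G23270 (3.03 ± 0.34) again rose most, followed by AT3G18250 at 2.41. S8H (AT3G12900), which encodes the hydroxylase that makes the coumarin fraxetin, rose by 2.13 ± 0.36 (adjusted p = 0.00159). RALFL27 rose by 2.08, the berberine bridge enzyme-like gene AT1G26410 by 2.06, the osmotin gene OSM34 (AT4G11650) by 2.01 and the ubiquitin ligase gene PUB19 (AT1G60190) by 2.01. AT4G21870 fell furthest, at −3.65 ± 0.27 (adjusted p = 7.76e-08), and AT2G41810 stood at −2.57 ± 0.25. AT5G28630 fell by 2.28, AT2G43140 by 2.16 and the peroxidase gene AT1G34510 by 2.06. AT5G54040 fell by 1.99, AT5G61590, an ERF transcription factor gene, by 1.80 and AT5G60760 by 1.77. EXPA18 (−1.13) and EXPA7 (−0.91) both fell. In the 10 earlier arrays alone, 232 probe sets were called, 231 of them among the 359, and each gene named in this paragraph kept its call. The count was 214 (60 higher and 154 lower) without replicate 2 of 12 h and 227 (121 and 106) without standard replicate 1. Without standard replicate 2 it was 301 (153 and 148), so the larger number of lower calls rests on both control arrays.

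After 24 h, 494 probe sets had changed, 220 higher and 274 lower, of which 235 named 1 gene. S8H rose from a signal of 44.7 ± 16.6 to 1595 ± 25.5 (mean ± SD, n = 2), a log2 fold change of 4.76 ± 0.36 with an adjusted p of 4.27e-08. AT5G25840 rose by 4.17 ± 0.24 and ATPMEPCRB (AT4G02330), which encodes a pectin methylesterase, by 3.75 ± 0.22. IMA1 rose by 3.01, bHLH101 by 2.79, AT2G41730 by 2.76, AT3G61930 by 2.65 and AT1G26380 by 2.56. AT4G21870 remained the gene with the largest fall, at −3.06 ± 0.27, and AT2G41810 stood at −2.72 and AT5G48430 at −2.38. AT2G43140 fell by 2.17, AT1G34510 by 2.12, AT5G60760 by 2.01 and AT5G54040 by 1.97. SWEET11 (AT3G48740), a sugar transporter gene, fell from 2447 ± 1280 to 574 ± 255, a log2 fold change of −2.03 ± 0.34. In the 10 earlier arrays alone, 371 probe sets were called, 152 higher and 219 lower, and 366 of them were among the 494. Each gene named in this paragraph kept its call there. The count was 303 (117 higher and 186 lower) without replicate 1 of 24 h, 253 (131 and 122) without replicate 2 of 24 h, 310 (172 and 138) without standard replicate 1 and 453 (233 and 220) without standard replicate 2, so which direction held more calls depended on single arrays.

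**Figure D2:**
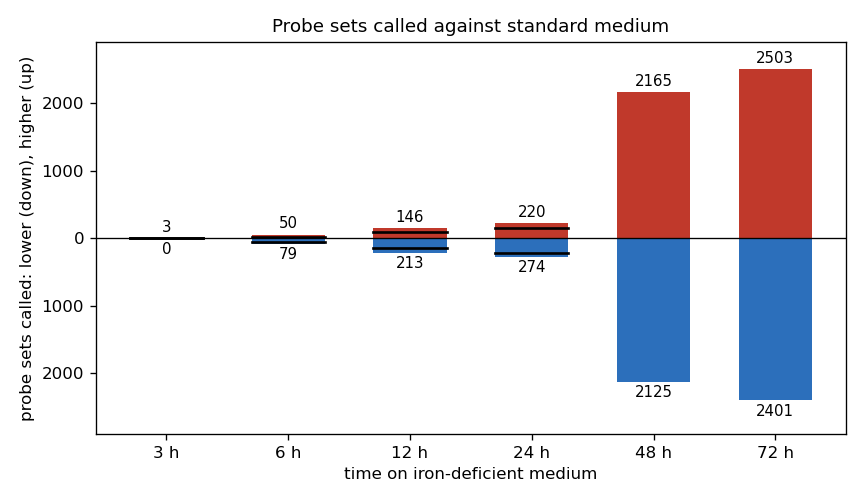
Probe sets called against standard medium at each time on iron-deficient medium, higher counts drawn upwards in red and lower counts downwards in blue, from the fit of all 14 arrays. Black lines give the counts from the 10 earlier arrays alone, 371 in all at 24 h; the 4290 and 4904 calls at 48 and 72 h compare arrays of different sets.

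At 48 h, 4290 probe sets differed from standard medium, 2165 higher and 2125 lower, and at 72 h 4904 did, 2503 higher and 2401 lower. These comparisons cross the 2 array sets, and the counts of 24 h and 48 h are not on the same footing. Of the 204 probe sets called between 3 h and 24 h within the earlier set, 93.1% had the same sign at 48 h. S8H was 6.53 ± 0.36 higher at 48 h and 6.79 ± 0.36 higher at 72 h, where its signal was 6570 ± 308 (mean ± SD, n = 2). AT5G25840 (5.49 at 48 h and 5.61 at 72 h), AT2G41730 (5.21 and 5.64), ATPMEPCRB (5.15 and 5.24), AT2G21640 (5.47 and 5.46) and AT2G23270 (5.05 and 4.91) were also among the largest rises at both times. AT1G26380 (5.03) and AT5G09570 (4.92) joined them at 48 h, and the late embryogenesis abundant protein gene AT3G02480 (5.41) and AT1G12030 (5.36) at 72 h. Among the largest falls at both times were AT2G41810 (−5.56 and −5.83), SWEET11 (−4.96 and −5.22), and the class III peroxidase genes AT1G34510 (−4.68 and −5.42) and PER35 (AT3G49960, −4.67 and −4.67). At 48 h these were followed by the peroxidase genes AT2G37130 (−4.16) and AT4G30170 (−4.15), the methionine sulfoxide reductase gene MSRB6 (AT4G04840, −4.14) and AT5G40510 (−3.90). At 72 h they were followed by the peroxidase gene AT4G26010 (−4.43), the dirigent protein gene AT4G11190 (−4.39), the lipid transfer protein family gene AT1G62510 (−4.30) and AT3G45700 (−4.30). AT2G43140, which fell at 6, 12 and 24 h, was at −0.55 and −0.28 and was not called. The count at 48 h was 2739 (1286 higher and 1453 lower) without replicate 1 and 2833 (1317 and 1516) without replicate 2 of 48 h, and at 72 h 3283 (1584 and 1699) without replicate 1 of 72 h, so the larger number of higher calls at these times was not stable. With each array centred on its median, the split was 1646 higher and 2587 lower at 48 h and 1888 higher and 2865 lower at 72 h.

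Other measures moved with the 48 and 72 h arrays. The green tissue markers RCA (AT2G39730), the activase of the carbon-fixing enzyme, and LHCB4.1 (AT5G01530), an antenna protein of photosystem II, were at −2.33 and −1.88 at 48 h and at −2.70 and −2.17 at 72 h. They stood between 0.06 and 0.50 at 3 to 24 h with no call. The root hair markers EXPA18 and EXPA7 were at −2.84 and −2.39 at 48 h and at −3.88 and −3.07 at 72 h. The mean ratio of 3′ to 5′ signal, a measure of RNA integrity and labelling, was 1.33 for actin on the later arrays against 2.05 on the earlier arrays, 1.62 against 2.16 for ubiquitin and 1.03 against 0.873 for GAPDH. The 25S ribosomal RNA probe set had a signal of 665 ± 403 on standard medium, 862 ± 147 at 24 h, 2781 ± 1436 at 48 h and 1750 ± 656 at 72 h (mean ± SD, n = 2).

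The list of iron uptake and coumarin secretion genes, fixed before the data were examined, had 4 of its 22 genes among the tested probe sets, and all of them rose by 24 h. They were S8H, BGLU42, a beta-glucosidase gene linked to coumarin release, F6'H1 (AT3G13610), which encodes the enzyme that starts scopoletin synthesis, and MTP8 (AT3G58060), a metal transporter gene. At 24 h, BGLU42 rose by 2.31, MTP8 by 1.91 and F6'H1 by 1.33 on the log2 scale, beside 4.76 for S8H. At 72 h the values were 6.79 for S8H, 3.45 for BGLU42, 3.30 for MTP8 and 1.90 for F6'H1. Over all genes tested, 0, 1, 2, 4, 4 and 4 members were called at 3, 6, 12, 24, 48 and 72 h. Adjusted over the list alone the numbers were 0, 2, 3, 4, 4 and 4. As a group the list moved upwards with camera at 6 h (adjusted p = 0.0317), 12 h (9.18e-06), 24 h (6.75e-13), 48 h (1.66e-06) and 72 h (3.30e-06). With an estimated correlation the adjusted p was 0.297 at 6 h, which ended that call, and 0.0405, 0.0126, 0.0375 and 0.0375 at the later times. In the earlier arrays alone it was 0.110 at 12 h, which ended that call too, and 0.0265 at 24 h. The call at 6 h was also lost without replicate 2 of 6 h (adjusted p = 0.347) or standard replicate 2 (0.245), with fry, with no filter, with no trend and with either other pseudocount. Without replicate 2 of 3 h the list was called downwards at 3 h (adjusted p = 0.0202). IRT1, FRO2 and FIT, the main iron transporter, reductase and regulator genes of the root, were not analysed here.

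The iron regulators and iron redistribution list had 11 tested probe sets for 10 of its 29 genes. At 24 h 5 of them rose: IMA1 (3.01), bHLH101 (2.79), the bHLH gene PYE (AT3G47640, 1.40), the ubiquitin ligase gene BTSL2 (AT1G18910, 0.87) and 1 of the 2 probe sets of its relative BTSL1 (AT1G74770, 1.21). At 48 and 72 h 7 probe sets were higher, with ILR3 (AT5G54680) at 0.66 and 0.71 and the other BTSL1 probe set at 1.77 and 1.88. bHLH104 (AT4G14410) was lower at 72 h, at −0.57, while bHLH34, bHLH115 and bHLH121 were called at no time, with values between −0.50 and 0.25. The members called higher over all genes were 1, 2, 2, 5, 7 and 7 from 3 to 72 h, and 1, 2, 3, 6, 7 and 7 adjusted over the list alone. Lower calls were 0 up to 48 h and 1 at 72 h, and adjusted over the list alone 1 at 12 h and 1 at 72 h. With camera the list moved upwards at 12 h (adjusted p = 0.0179), 24 h (2.20e-08), 48 h (2.58e-05) and 72 h (3.84e-05). With an estimated correlation the adjusted p was 0.126 at 12 h, which ended that call, 0.0126 at 24 h and 0.0328 at 48 and 72 h. The call at 12 h was also lost without standard replicate 2 (adjusted p = 0.245), and without standard replicate 1 the list was called at 6 h (adjusted p = 0.0132). At 3 h the list was not called, and its mean (0.08) and median (−0.06) differed in sign. Between 3 h and 24 h, which involves neither the control nor the later set, the iron uptake list moved by a mean of 2.73 and this list by 0.83, each with an adjusted p of 0.00641 with an estimated correlation. That comparison was added after the data had been seen.

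**Figure D3:**
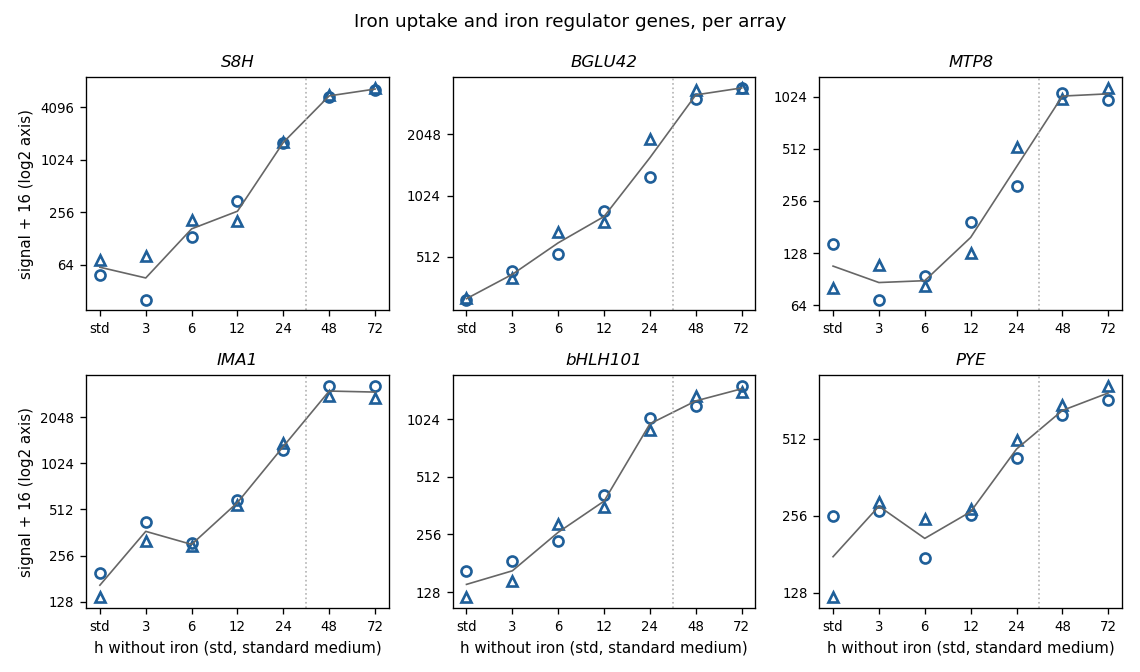
Signal + 16 (log2 axis) of 6 iron genes on each array, for standard medium (std) and hours without iron, with circles for replicate 1, triangles for replicate 2 and a line through the group means of log2 values. The dotted line parts the array sets; S8H rises from 44.7 on standard medium to 1595 at 24 h and 6570 at 72 h (mean signals without the added 16).

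The 3 tested members of the phenylpropanoid and lignin list moved apart. HCT (AT5G48930), of the lignin branch, rose by 1.20 at 48 h and 1.52 at 72 h, and COSY (AT1G28680), which makes coumarins, by 0.66 and 0.98. F6'H2 (AT1G55290), a relative of F6'H1, fell by 1.23 and 1.46. The list was called with camera at no time, and its adjusted p at 72 h was 0.413 (with an estimated correlation, adjusted p = 0.503), while fry gave an adjusted p of 0.0443 there. From 3 to 24 h 0 members were called, and adjusted over the list alone 1 was lower at 3 h and, at 24 h, 2 were higher and 1 lower. At 3 h its mean (−0.22) and median (0.03) differed in sign. In all, 18 tests were made on these 3 lists, of which 9 were called with camera, 7 of them also with an estimated correlation and 8 also with fry. In the earlier arrays alone 5 of 12 tests were called, 2 of them also with an estimated correlation and 3 also with fry.

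Other fixed lists had fewer than 3 tested probe sets and are given gene by gene. SAPX (AT4G08390), a chloroplast and mitochondrial ascorbate peroxidase that needs heme iron, fell from 1233 ± 391 to 550 ± 4.63 at 24 h, a log2 fold change of −1.11, and was at −2.47 at 48 h and −3.19 at 72 h. The zinc transporter gene ZIP9 (AT4G33020) was higher at 48 h (1.44) and 72 h (1.26). The formate dehydrogenase gene FDH (AT5G14780), of the methionine cycle list, was at −1.81 and −1.93 at these times, and the clock gene GI (AT1G22770) at 0.78 and 1.17. WRKY53 (AT4G23810) and ZAT10 (AT1G27730), of the touch and wounding list, were at 1.29 and 1.34 at 48 h and at 1.37 and 1.39 at 72 h. None of ZIP9, FDH, GI, WRKY53 and ZAT10 was called at 3 to 24 h. As the only tested members of their lists, SAPX was also lower at 12 h and ZIP9 higher at 24 h (0.55) at an unadjusted limma p under 0.05. Adjusted over the list alone, 1 of the 2 touch genes was higher at 3 h and both root hair markers were lower at 3 and 6 h. CCS1 (copper list), EIN3 (ethylene list) and the reference genes SAND and TIP41L were called at no time against standard medium, with values between −0.27 and 0.39. Over all genes the endodermis marker SGN3 and the dividing cell marker MCM7 were also called at no time against standard medium, while SGN3 was higher at 48 h than at 24 h (0.48), across the array sets. EIN3 and SGN3, also the only tested members of their lists, were each higher at 72 h at an unadjusted limma p under 0.05. The phosphate starvation, suberin, non-hair epidermis, stele and root cap lists had 0 tested probe sets and were not analysed here. In all, 27 of the 193 genes of the fixed gene lists and 6 of the 66 marker genes were tested.

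**Figure D4:**
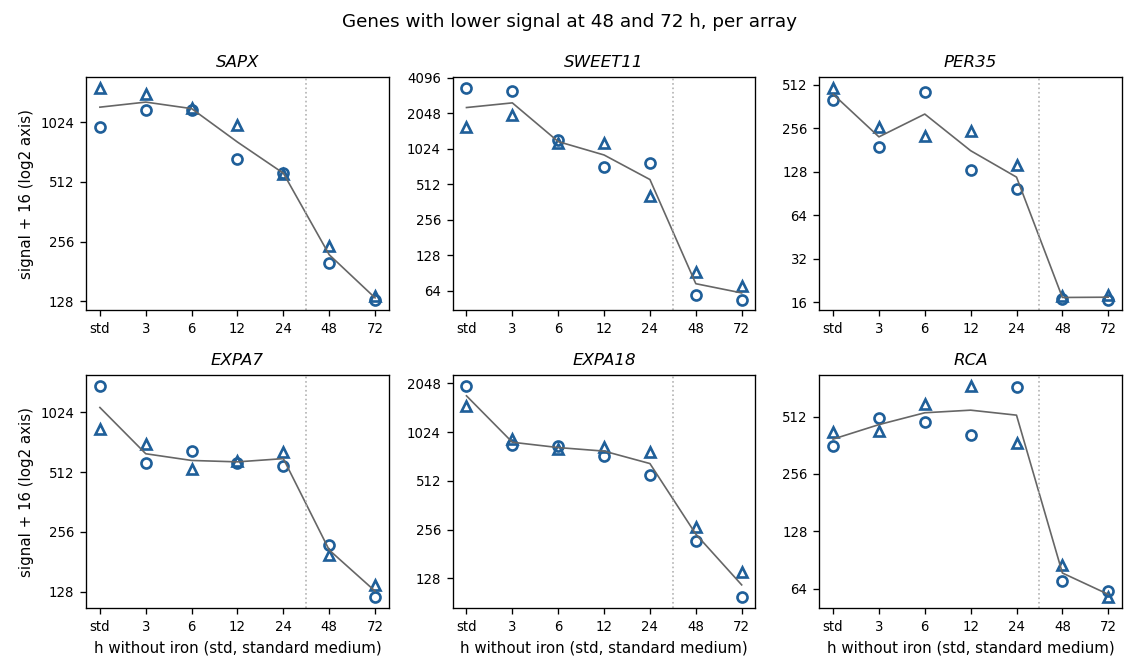
Signal + 16 (log2 axis) of 6 genes on each array, for standard medium (std) and hours without iron, with circles for replicate 1, triangles for replicate 2 and a line through the group means of log2 values. The dotted line parts the array sets; SAPX and SWEET11 are lower at 24 h already, while RCA is called lower at 48 and 72 h only.

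Neighbouring times were compared directly, which needs no control array. From 3 h to 6 h, 30 probe sets changed, 7 higher and 23 lower. AT2G23270 rose by 2.15, S8H by 1.87, AT1G51920 by 1.73, AT1G26380 by 1.49 and AT5G67430 by 1.21, while AT4G21870 fell by 2.64, AT5G48430 by 1.74, the transcription factor gene NAC014 by 1.33, AT2G44370 by 1.26 and the receptor kinase gene AT1G51850 by 1.26. In the earlier arrays alone 13 were called, all lower, and of the genes just named AT4G21870, AT5G48430 and AT2G44370 kept their calls. The count was 7 (1 higher and 6 lower) without replicate 1 of 3 h, 16 (4 and 12) without replicate 1 of 6 h and 23 (12 and 11) without replicate 2 of 3 h. From 6 h to 12 h, 6 probe sets rose and 0 fell. OSM34 rose by 1.80, AT5G25840 by 1.59, AT2G15220 by 1.38, AT5G10070 by 1.13 and the chitinase gene CHI (AT2G43570) by 0.98, and the other probe set, with no gene in the table used and chosen after its values were seen, by 1.25. OSM34 and AT2G15220 kept their calls among the 3 of the earlier arrays alone. The count was 26, all higher, without replicate 2 of 6 h, and 2 without either replicate of 12 h, higher without replicate 1 and lower without replicate 2, and 964 probe sets had an unadjusted p under 0.05 with limma.

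From 12 h to 24 h, 51 probe sets changed, 44 higher and 7 lower. S8H rose by 2.62, ATPMEPCRB by 2.49, AT3G02480 by 2.48, AT5G25840 by 2.42 and AT2G21640 by 2.03, and AT3G20510 fell by 0.84. In the earlier arrays alone 28 were called, and AT2G21640 and AT3G20510 were not among them. The count was 29 (25 higher and 4 lower) without replicate 1 and 10, all higher, without replicate 2 of 24 h. From 48 h to 72 h, 2 probe sets changed, of which the lipid transfer protein family gene AT3G58550 rose 2.83-fold and a probe set with no gene in the table used, chosen after its values were seen, fell by 1.39 on the log2 scale. With limma 568 probe sets had an unadjusted p under 0.05 in this comparison, and the count was 51, 23 higher and 28 lower, in a fit of the 4 later arrays alone. It was 0 without replicate 2 of 48 h, 1 without either replicate of 72 h and 5 to 7 without 1 array of the standard, 3 h or 6 h groups.

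From 24 h to 48 h, across the array sets, 3238 probe sets differed, 1509 higher and 1729 lower. The largest rises were in the peroxidase gene AT4G36430 (4.29), the isocitrate lyase gene ICL (AT3G21720, 4.15) of the glyoxylate cycle, AT2G32190 (3.76), the peroxidase gene AT5G39580 (3.63) and AT1G65500 (3.55). The largest falls were in MSRB6 (−3.97), AT2G26690, a nitrate and peptide transporter family gene (−3.63), AT4G25250 (−3.56), AT2G37130 (−3.40) and AT4G30170 (−3.13). With each array centred on its median the split was 1145 higher and 2065 lower. The count was 2027 and 2099 without replicate 1 and 2 of 24 h, and 1871 and 1907 without replicate 1 and 2 of 48 h.

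Taking all 6 times at once, 5295 probe sets changed by the F test of limma, which takes in 48 h and 72 h across the array sets. In the earlier arrays alone the F test over 3, 6, 12 and 24 h called 326. Of the probe sets called at 3 to 24 h, 3 were first called at 3 h, 127 at 6 h, 256 at 12 h and 247 at 24 h, 633 in all. The calls at 12 h and 24 h shared 241 probe sets in the same direction and 0 in opposite directions. Independent lists of these sizes would share 6.63. Of the probe sets called at 12 h, 99.7% had the same sign at 24 h. In unchanged groups simulated against the same controls, 66.6% of all probe sets did. These shares are not matched, since picking calls made against shared controls raises sign agreement even without change. The correlation of the fold changes at 12 h and 24 h across probe sets, which are not independent replicates, was 0.716 against 0.501 in the simulation, and the covariance was 0.108 against 0.0299. The calls at 24 h and 48 h shared 389 in the same direction and 18 in opposite directions, where independent lists would share 77.6. Across the array sets, 91.1% of the probe sets called at 24 h had the same sign at 48 h. The simulation gave 66.6% over all probe sets, which again is not matched. Part of each overlap may come from the shared controls. With 1 control array for each time, so that none is shared, 12 h and 24 h shared 113 in the same direction and 0 in opposite directions in either arrangement (independent lists 3.49 and 3.72; correlation 0.358 and 0.336; covariance 0.0681 and 0.0646). For 24 h and 48 h it was 278 and 233 in the same direction and 17 and 14 in opposite directions (independent lists 52.4 and 40.7, covariance 0.147 and 0.145). The same sign was then held at 24 h by 89.5% and 93.8% of the calls at 12 h. At 48 h it was held by 85.0% and 87.5% of the calls at 24 h. This division was chosen after the data had been seen, and each control is then 1 array. The shared count of 12 h and 24 h was 152 without replicate 2 of 12 h, 154 and 153 without replicate 1 and 2 of 24 h, and 160 without standard replicate 1.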

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

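All tests in this part were chosen after the results they bear on had been seen. The number of called probe sets went from 494 at 24 h to 4290 at 48 h, where the array set changes. The scaling of the later arrays as the whole cause is argued against by 3905 calls at 48 h after quantile normalization, beside 495 at 24 h, and the lower spread of those arrays by a median absolute log2 fold change of 0.390 at 48 h against 0.199 at 24 h. Of the 204 probe sets called between 3 h and 24 h within the earlier set, 93.1% (exact 95% interval 88.8% to 96.2%) had the same sign at 48 h. This argues against the array set as the whole cause of their own change at 48 h. They bear little on the rise in calls, since 173 of them were called at 24 h in the same direction in the earlier arrays alone. The interval treats probe sets measured on the same arrays as independent, so it does not measure the spread between replicates. For the other 4111 probe sets called at 48 h, criteria on the correlation given next differed. The stricter, which asked for a higher correlation, left the array set open. The looser asked only for more than replicate differences gave. It argued against the array set as the whole cause, if no technical difference of the same kind runs within the earlier set. The change from 3 h to 24 h and the change at 48 h, which share no array, correlated at 0.469 (69.8% with the same sign). The correlation was 0.398 or above with any 1 of the 8 arrays left out, where replicate differences reached 0.13 at most. Replicate differences hold only the noise within a group, so they do not show what a technical difference between groups would give. The 4111 also still held probe sets called at 24 h against standard medium, which can raise the correlation. As the cause of a part of these changes the array set cannot be told apart from iron deficiency, since no group had arrays in both sets. A technical difference within the earlier set was not tested, and this limit also holds for the 204 probe sets. At 24 h the spike-in signal was 0.833 times that of the other 8 earlier arrays. The first principal component at 24 h, −14.2 and −12.0, lay nearest to the later set. Longer iron deficiency and root age remain open and were not tested.

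Root hair cell wall and peroxidase genes, a list made after the data had been seen, were lower as a group at every time with camera, from a shift of −0.68 at 3 h to −2.37 at 72 h. The estimated correlation kept the call at 12 h alone (adjusted p = 0.0407, but 0.0637 in the earlier arrays alone), and gave an adjusted p of 0.0561 at 3 h. Within the later set, with no control array, the list moved by a mean of −0.46 between 48 h and 72 h, with 10 of 12 members below 0 (fry p = 0.12; camera adjusted p = 1.45e-06, and 0.522 with an estimated correlation), where a fit of these 4 arrays alone called EXPA18 (−1.04) and AT5G04960 (−1.08) lower and AT1G26250 (1.13) higher, and within the earlier set by −0.27 between 3 h and 24 h, with 9 of 12 below 0 (camera adjusted p = 0.0577, and 0.537 with an estimated correlation). These values leave open, as possible causes of the whole pattern, the 2 control arrays at every time and the array set at 48 h and 72 h, since standard medium and 3 to 24 h lie in one set. A change in root hair growth with iron deficiency or age was not tested.

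The 5 tested photosynthesis genes were lower at 48 h and 72 h and showed no call at 3 to 24 h. Within the later set they moved by a mean of −0.37 between 48 h and 72 h, 5 of 5 below 0, with a fry p of 0.0717, so the array set cannot be told apart from a change with time. Less green tissue in the samples would lower the members alike, and their SD at 48 h was 0.534 beside a mean SE of 0.298, with 5 of 5 called lower, which leaves that explanation open. A response of these genes to low iron is also possible and was not tested.

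Of 507 probe sets called both at 3 to 24 h and at 48 or 72 h, 42 were called in opposite directions. Those among the genes named by rule, with a called difference between the times, are given as values, and each pair of times crosses the array sets. AT4G36430, a peroxidase gene, went from −1.31 at 24 h to 2.98 at 48 h, a difference of 4.29. ICL went from −1.54 to 2.62, a difference of 4.15, and its call at 24 h was not kept in the earlier arrays alone. AT1G68620 went from 1.03 to −0.89, a difference of −1.92. AT1G05700 went from −1.19 to 1.21, a difference of 2.40. AT2G26690 went from 1.99 to −1.65, a difference of −3.63. AT2G44370 went from −0.85 at 6 h to 0.61 at 72 h, a difference of 1.46. The 25S ribosomal RNA control probe set, outside the tests, had a mean signal of 2781 at 48 h and 1750 at 72 h, above the 665 on standard medium.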

How the results depend on the processing

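The fit of the 10 earlier arrays, every alternative for the overlap of calls, and quantile normalization and left-out arrays for the list tests were chosen after the data had been seen, and the others before. Among the largest rises and falls, 114 values in all, none turned direction with quantile normalization or median centring. Under the other alternatives run none could. The naming rule had put both arrays of a group on the same side of both arrays of the other. Calls lost were 3 with quantile normalization, 2 with median centring, 6 with a pseudocount of 64, 16 with no filter and 0 with the replicate block. A pseudocount of 1 lost 3 of 110, the earlier arrays 17 of 71, and 31 were lost when some array was left out. Of the 9 calls on fixed lists, 2 were lost with an estimated correlation, 1 each with fry (which also gained 1), no filter, no trend and either pseudocount, and 0 with quantile normalization or median centring. Total counts not given here stayed within 1.5 times, while counts by direction moved further in places. The cause of each shift was not tested. The fits of the earlier arrays and of the 4 arrays compared hold fewer arrays, and the spread also differs between the sets. The median residual SD was 0.235 in the earlier arrays, 0.146 in the later arrays and 0.222 in all 14. Between 48 h and 72 h the fit of the 4 later arrays called 51, against 2 in all 14. Fewer arrays alone do not account for that rise. Low signal limits the values near the filter level of 49.6.

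With a 2-fold threshold the counts were 221 at 12 h, 317 at 24 h, 1888 at 48 h, 2219 at 72 h and 1339 between 24 h and 48 h. Adjusted over the whole family they were 178 at 3 h, 413 at 6 h, 608 at 12 h, 107 between 3 h and 6 h, 65 between 6 h and 12 h, 114 between 12 h and 24 h, 2017 between 24 h and 48 h and 69 between 48 h and 72 h. In such a pooled adjustment the many calls of the comparisons across the array sets ease the threshold for the other comparisons. The higher counts are therefore no evidence of more change at the early times. In the earlier arrays alone the counts were 1 at 3 h, 67 at 6 h, 232 at 12 h, and 13, 3 and 28 between neighbouring times up to 24 h. The F test called 326 there, over 3 to 24 h only, so it is a different test from that over the whole time course. With only the 4 arrays compared they were 1 at 3 h, 58 at 6 h, 140 at 12 h, 11 between 3 h and 6 h, 30 between 12 h and 24 h and 51 between 48 h and 72 h. The count at 3 h was 1 with quantile normalization, median centring or no filter and 0 with no trend in limma, where 3 were called and 993 had an unadjusted p under 0.05 as reported. With no filter the count was 78 at 6 h, 15 between 3 h and 6 h, 2 between 6 h and 12 h and 33 between 12 h and 24 h, and with no trend it was 81 at 6 h, 2 between 6 h and 12 h and 23 between 12 h and 24 h. Between 48 h and 72 h it was 16 and 9 with pseudocounts of 1 and 64, 7 with quantile normalization and 4 with a robust prior.

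Leaving out each array in turn gave 1 to 23 at 3 h, 67 to 151 at 6 h, 214 to 378 at 12 h, 253 to 545 at 24 h, 2739 to 4537 at 48 h, 3283 to 5159 at 72 h and 4181 to 5597 over the time course. Between neighbouring times it gave 7 to 44, 2 to 26, 10 to 60, 1871 to 3466 and 0 to 7 in order of time, 152 to 259 for the overlap of 12 h and 24 h, and 7 to 10 called list tests. Higher and lower calls ranged from 1 to 15 and 0 to 14 at 3 h, 20 to 60 and 26 to 94 at 6 h, 60 to 153 and 106 to 226 at 12 h, 117 to 241 and 122 to 304 at 24 h, 1286 to 2300 and 1453 to 2238 at 48 h and 1584 to 2653 and 1699 to 2507 at 72 h, and between neighbouring times from 1 to 14 and 6 to 32, 0 to 26 and 0 to 2, 10 to 51 and 0 to 9, 794 to 1627 and 1077 to 1839, and 0 to 3 and 0 to 4. Against standard medium the larger side turned at every time when some array was left out. From 12 h to 24 h the higher side stayed the larger with any array left out. With 1 control array for each of 12 h and 24 h the overlap was 113 in either arrangement. A group left with 1 array is assumed to vary like the others. Median centring moved the split at 48 h from 2165 higher of 4290 to 1646 higher and 2587 lower, at 72 h to 1888 and 2865, and between 24 h and 48 h to 1145 and 2065. With quantile normalization the split was 1828 and 2077 at 48 h and 2105 and 2275 at 72 h, and with no filter 2028 and 2182, and 2378 and 2509.

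Arrays share replicate numbers, which were not taken as pairs: over 21 pairs of groups the deviations of same-numbered arrays correlated from −0.14 to 0.27, 4 of them above 0.1. A hint of a link is in the data, since 12 of 14 arrays matched their own number best and the 25S ribosomal RNA signal was higher in replicate 1 in 7 of 7 groups. The deviations of the 2 arrays of a group mirror each other, so the 14 matches are not separate evidence. With the replicate block the count between 48 h and 72 h was 7 in place of 2, and no other total count moved by over 1.5 times.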

Other observations

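All lists and tests in this part were chosen after the data had been seen. The core hypoxia response list had 28 genes, 14 of them with a probe set paired with 1 gene, of which 7 were tested. The filter used the mean of all 14 arrays, so a gene low at the early times could pass through high values at 48 h and 72 h. The 7 tested genes rose together at 48 h and 72 h, 7 of 7 called at both times. Of all 13648 probe sets tested, 2165 were called higher at 48 h and 2503 at 72 h. AT4G10270 was at 3.98 and 4.66, AT3G27220 at 3.09 and 3.73 and AT4G27450 at 2.59 and 2.77. The group moved upwards with camera at 24 h (adjusted p = 0.00923; with an estimated correlation, adjusted p = 0.116), where AT5G44730 rose by 1.35 (a call not kept in the earlier arrays alone), and at 48 h and 72 h (adjusted p = 0.0316 with an estimated correlation at both). Further loci known to respond to iron rose with time: 1 of 14 at 6 h, 5 at 12 h, 11 at 24 h and 13 at 48 h and 72 h. Among them AT5G05250 rose by 1.58 at 24 h and 2.77 at 72 h, AT5G38820 by 1.54 and 2.77, AT3G07720 by 1.77 and 1.72, and UGT72E1 by 1.08 and 2.16. With camera and an estimated correlation the adjusted p was 0.0604 at 12 h, 0.0316 at 24 h (0.0637 in the earlier arrays alone) and 0.0561 at 48 h and 72 h, and with the preset correlation the list was called at each of these times. In the earlier arrays alone 0 members were called at 6 h, 2 at 12 h and 10 at 24 h. Of the 10 tested mitochondrial electron transport and iron-sulfur assembly genes, 2 fell at 24 h (1 in the earlier arrays alone) and 4 at 48 h and at 72 h, and 0 rose, with a median of −0.10 at 48 h and −0.11 at 72 h. The cytochrome c gene CYTC-2 fell by 0.89 at 24 h and by 2.12 at 48 h, and the iron-sulfur subunit genes SDH2-1 and SDH2-2 of succinate dehydrogenase fell by 1.42 and 1.87 at 72 h. With camera that list was called at no time (lowest adjusted p = 0.0661, at 72 h), while fry, which does not compare a list with other genes, gave an adjusted p of 0.000948 at 48 h and 0.000603 at 72 h. The 48 h and 72 h values cross the array sets.

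Of the 81 cytosolic ribosomal protein probe sets, 40 fell and 3 rose at 48 h and 51 fell and 3 rose at 72 h, while 0 were called at 3 to 24 h. The list does not hold the acidic ribosomal protein gene AT4G00810, which rose at 3 h (1.12, a call not kept in the earlier arrays alone) and 24 h (0.87). As a group they shifted by 0.23 at 3 h (adjusted p = 9.09e-12), 0.21 at 6 h and 0.19 at 12 h and by −0.47 at 48 h and −0.57 at 72 h, and with an estimated correlation the adjusted p was 0.436, 0.471, 0.502, 0.471 and 0.442. The 25S ribosomal RNA signal was 2781 at 48 h. Photosynthesis genes shifted by −1.60 at 48 h and −1.97 at 72 h, with PSAE1 at −1.55 and −2.03, PSBW at −1.12 and −1.55 and LHCB4.3 at −1.06 and −1.34. The adjusted p was 0.00106 and 0.000347 with camera, 0.336 and 0.297 with an estimated correlation and 0.00217 and 0.000727 with fry. Of the 12 root hair cell wall and peroxidase genes 0, 3, 10, 6, 10 and 10 fell from 3 h to 72 h, and in the earlier arrays alone 0, 2, 8 and 5 at 3 to 24 h. Cell division genes shifted by 0.26 at 3 h, with 0 called, and by −0.52 at 72 h, where 4 of 12 fell. Their adjusted p was 0.0149 and 0.0426 with camera, 0.442 and 0.481 with an estimated correlation and 0.246 and 0.0277 with fry. Of 7 XTH genes, which remodel xyloglucan, 5 fell and 1 rose at 48 h (adjusted p = 0.0426, and 0.222 with an estimated correlation), a call that median centring ended (adjusted p = 0.0604). The 7 RALF peptide genes shifted by 0.44 at 3 h (adjusted p = 0.0111, and 0.198 with an estimated correlation), with 0 called, and were not called as a group with camera at later times, where 3 fell and 1 rose at 48 h (shift −0.47, adjusted p = 0.181) and 4 fell and 1 rose at 72 h. Suberin genes (2 rose and 1 fell at 48 h), expansins (1 and 4), UGT (7 and 9), BGLU (2 and 2), GSTU (2 and 3), SCPL (3 and 3), SWEET (0 and 2) and CYP (2 and 5) genes were called as groups with camera at no time, except expansins at 48 h with quantile normalization (adjusted p = 0.0422). With fry the adjusted p at 48 h was 0.000356 for expansins, 0.00219 for GSTU, 0.00858 for SWEET, 0.0194 for CYP, 0.0258 for BGLU and 0.0273 for UGT, and 0.0373 for SCPL at 72 h, while suberin genes were not called. For RALF genes fry gave 0.0366 at 3 h and 0.0387 at 12 h, both upwards, calls not kept in the earlier arrays alone (0.228 and 0.240). It gave 0.0152 at 48 h and 0.0251 at 72 h, both downwards, and for XTH genes 0.000330 at 48 h and 0.000287 at 72 h. The mean and median of the BGLU list differed in sign at 24, 48 and 72 h. The xylem and phloem genes IRX10 and IRX15L and the 1 Aux/IAA probe set were not called. In all, 24 of 102 tests on these lists were called with camera, 4 of them also with an estimated correlation and 20 also with fry. In the earlier arrays alone 12 of 68 were called, 0 of them also with an estimated correlation and 3 also with fry.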
